A study of Mus musculus with 6 samples.

How the data were processed

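The data are 6 single-channel MoGene 1.0 ST arrays of mouse KSL SLAM cells, 3 from PBS-treated and 3 from G-CSF-treated mice. Per the labels, each array came from an independent pool of 5 to 10 mice, RNA was purified on columns, amplified with the NuGen Ovation system and labelled with biotin. The deposited values are intensities of 35554 probesets, processed by RMA per the submitters' processing notes. RMA as it is defined corrects the background, applies quantile normalization across arrays and summarises the probes of a probeset. Its software, its version and the set of arrays normalized together are not given in the sources used here. The deposited intensity values ran from 2.7 to 19069 with a median of 58.8, so they are on a linear scale. The design fixed before the data were examined had assumed log2 values, so log2 was taken first and the planned test was kept. Column quantiles of the arrays differed slightly (medians 56.2 to 61.7), and the SD of log2 intensity ran from 1.79 (G-CSF replicate 1) to 1.95 (G-CSF replicate 2). Quantile normalization again was among the alternatives fixed before the data were examined.

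Probesets were named through the platform annotation, with gene identifiers looked up in a RefSeq gene table (assembly GRCm38.p6), which held 21698 of the 21789 identifiers. The table served for names only, and no coordinates are given because the genome build behind the annotation is not given in the sources used here. Of the probesets, 21789 had 1 gene symbol, 1621 had several and 12144 were not listed, and only those with 1 symbol were assigned to a gene. The lowest 25% of these by mean over all 6 arrays (a log2 mean up to 5.152) were left out. The probeset with the highest mean stood for each gene, which left 14994 genes. Probesets with several symbols or none were tested separately. Ly6a and Cdkn1a were named in advance and had no probeset with 1 symbol, so they are not analysed here.

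Groups were compared with limma (version 3.58.1 in R 4.3.3) by lmFit and eBayes with default settings, with no covariate, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05, two-sided. Prior degrees of freedom were 3.23 and the median residual SD was 0.256 on the log2 scale. A signed difference is G-CSF minus PBS. The 31 gene lists were written before the data were examined, and of their 1040 entries 912 matched a probeset. Lists with at least 8 measured members were tested with camera at a preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation, on ranks and with fry. With an estimated correlation 0 lists passed (smallest adjusted p = 0.15). By fry's directional test, which asks whether a list's genes move one way on balance, 0 lists passed (smallest adjusted p = 0.0681). By fry's mixed test, which asks for change in either direction, 12 did. Among these, camera had not called the niche retention and adhesion (mixed adjusted p = 0.00189), sort marker (0.0125), NF-kB (0.0125), type I interferon (0.0197) and antioxidant (0.0218) lists. Array means of each list were also compared by an exact two-sided permutation test. Figures were drawn with matplotlib 3.10.9.

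The genes named in the text were chosen by a rule set before the data were examined. It takes up to 12 genes in each direction with the largest differences among genes past the threshold without overlap between groups. Fewer are filled to 12 with the largest differences among genes at an unadjusted p under 0.01 without overlap, which are said not to pass. Where a group's mean lay under 5.152, its arrays below that limit were raised to it and the difference is given as "at least", beside a p of the measured values, a rule added after seeing the data. Such a value allows for the limit and not for sampling error, so the true difference can be smaller. The limit is the filter's and no measured background. The rule for naming genes adds up to 4 members per list with the smallest p, and 16 genes regardless of their result. Symbols of predicted genes and small RNAs were passed over, which left out 1 gene among the negative differences. S100a8, S100a9, Ly6g, Prtn3, Ms4a3 and Ncf1 fall outside the rule and were chosen after their values were seen.

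The fit was tested on simulated arrays with the residual SDs of the 14994 genes shuffled over genes, in 10 runs with 50 genes changed at each size. It recovered 38.4% of genes changed by 1 on the log2 scale, 81.4% at 2, 94.2% at 3 and 96.8% at 4, with a median of 7.5 false calls. The noise was normal and independent between genes, so these shares do not give the power of the comparison in the measured arrays. Camera found all 5 lists shifted by 0.5 and called 0.1 of 25 unshifted lists per run, with genes simulated as independent. Alternatives changed 1 choice at a time, namely the filter, the normalization, the variance model, array weights, the probeset rule, the replicate number as a block, a minimum fold of 1.5, and leaving out each array. Tests of lists without members shared with the neutrophil and progenitor lists were added after seeing the data. The annotation of probesets can be old, cross-hybridisation between close paralogs was not resolved, and amplification from small cell numbers can add noise that the replicate SDs include.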

Results

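Gene expression was measured with MoGene 1.0 ST arrays in KSL SLAM cells, a bone marrow fraction enriched for haematopoietic stem cells that was gated as lineage-negative, c-Kit-positive, Sca-1-positive, CD150-positive, CD48-negative and CD41-negative. The mice had received granulocyte colony-stimulating factor (G-CSF, 125 mcg/kg, 2 subcutaneous injections per day) or PBS for 7 days. Each group had 3 arrays, each from an independent pool of 5 to 10 mice. The median intensity per array lay between 56.2 and 61.7, and Spearman's rho between arrays over the 14994 genes tested was 0.861 to 0.895 within groups and 0.836 to 0.892 between groups. With 3 arrays per group, the number of arrays limits the precision of each difference.

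The comparison asked which transcripts differ between stem cell fractions of G-CSF-treated and PBS-treated mice. Slfn4, a Schlafen family gene, rose by 3.08 on the log2 scale (SE 0.21, 8.43-fold, limma adjusted p = 0.00947), from 5.83 ± 0.25 to 8.90 ± 0.28 (mean log2 intensity ± SD, n = 3 per group). Lilr4b, an immunoglobulin-like receptor of myeloid cells, rose by 2.24 (SE 0.15, adjusted p = 0.00947), and its SD was 0.09 with PBS and 0.12 with G-CSF. Wfdc17, which encodes a secreted protein with a WAP domain, rose by 3.31 (SE 0.31, adjusted p = 0.0391). Ly6a2, of the Ly6 family, rose by 2.01 (SE 0.19, adjusted p = 0.0391). In each of these 4 genes, all 3 G-CSF arrays lay above all 3 PBS arrays. These were the genes that passed at an adjusted p under 0.05, and 0 genes were lower at that threshold by limma, where the smallest adjusted p was 0.115. At an unadjusted p under 0.05 there were 410 higher and 495 lower genes, against 750 expected by chance in all. Leaving out 1 array ended all 4 calls in 5 of the 6 cases. The smallest adjusted p of any gene was then 0.104 without PBS replicate 1, 0.0815 without PBS replicate 2, 0.0703 without PBS replicate 3, 0.0842 without G-CSF replicate 2 and 0.0547 without G-CSF replicate 3. Without G-CSF replicate 1, 6 genes were higher, 3 of the 4 among them, and the adjusted p of Ly6a2 was 0.13. Centring the arrays on the median also ended the calls of Wfdc17 and Ly6a2 (adjusted p = 0.0831 each), whose adjusted p over all alternatives ran from 0.0267 to 0.182 and from 0.0314 to 0.182. The replicate number as a block ended the call of Ly6a2 too (limma adjusted p = 0.0781).

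To fill the count of 12, a further 8 genes with the largest positive differences among the rest had no overlap between the groups and an unadjusted p under 0.01, and did not pass after adjustment. In 4 of them the PBS mean lay under the filter's limit of 5.152, so their differences are given against that limit and their order of size is not settled. The words "at least" refer to the limit only and allow for no sampling error. On the log2 scale, limma's 95% intervals of the measured differences began lower. They began at 2.998 for Saa3 (3.685 against the limit), 2.652 for Stfa3 (3.281), 2.021 for Stfa2 (2.411) and 1.937 for Lipg (2.47). The acute-phase gene Saa3 was at 8.96 ± 0.88 with G-CSF (at least 12.9-fold higher, adjusted p = 0.0627), the stefin A protease inhibitor Stfa3 at 8.64 ± 0.89 (at least 9.72-fold), Stfa2 at 7.63 (at least 5.32-fold) and Lipg (endothelial lipase) at 7.62 (at least 5.54-fold). Of the 3 PBS arrays, 1 lay above the limit for Saa3, Stfa3 and Stfa2 each, and 0 for Lipg. Ifitm6 differed by 3.09, the neutrophil chemokine receptor Cxcr2 by 2.97, Lrg1 by 3.13 and the interleukin 1 family cytokine Il1f9 by 3.09. Apart from the replicate block, Saa3 passed with quantile normalization again (adjusted p = 0.0314, range over alternatives 0.0314 to 0.273), and without G-CSF replicate 1 so did Il1f9 (0.0371, range 0.0371 to 0.526) and Lipg (0.0364, range 0.0364 to 0.488). Stefin A genes are close paralogs, so their probesets may share signal. Of the 12 genes chosen in the same way for negative differences, 0 passed after adjustment. Cyb5a (cytochrome b5) differed by -2.10 (SE 0.35, adjusted p = 0.185), Pf4 (platelet factor 4) by -1.92 (SE 0.37), Pcbd1 by -1.84, Etv3 by -1.76 (adjusted p = 0.115), Mospd1 by -1.72 and the cation channel Trpc6 by -1.68. Kti12 (-1.65), the platelet protein multimerin Mmrn1 (-1.53), Ing2 (-1.52), the cell cycle transcription factor E2f3 (-1.50), Sar1a (-1.43) and Zdhhc4 (-1.42) followed. At an unadjusted p under 0.01, 30 genes were at least 4-fold higher and 1 was at least 4-fold lower in measured values, dim genes included.

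**Figure D1:**
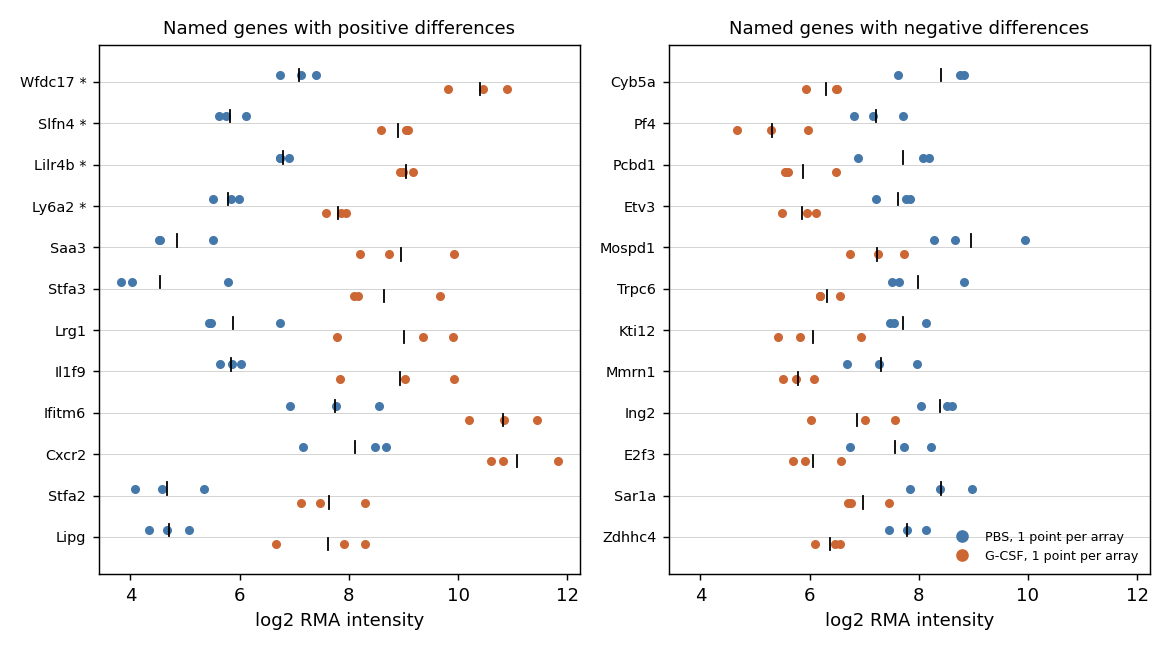
Log2 RMA intensity (horizontal axis) of the 12 genes named for positive and the 12 named for negative differences, with genes past the threshold taken first and the rest filled by measured size, and with 1 point per array and a vertical bar at each group's mean of 3 arrays. The 4 genes marked with an asterisk passed at an adjusted p under 0.05, and in all 24 genes shown the groups do not overlap, as the choice of genes required.

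Transcripts of neutrophils and their progenitors were higher with G-CSF as a group. Of the 29 measured members of the mature neutrophil list, 24 rose when adjusted over the list alone, and in 25 the groups did not overlap, where chance separates 10% of genes in either direction. In each of these 25 the G-CSF arrays were the higher ones. The list's median log2 difference was 1.53 (camera adjusted p = 3.4e-31, and adjusted p = 0.15 with an estimated correlation). Ltf (lactoferrin) rose by 2.16 (SE 0.29), Stfa2 by at least 2.41 and Ifitm6 by 3.09, each adjusted over the list alone. S100a9 and S100a8, the calprotectin genes that neutrophils are known to express abundantly, were named after their values were seen and rose by 0.81 and 0.95 adjusted over the list alone. Ly6g, a surface marker of neutrophils also named afterwards, differed by -0.19 (SE 0.48, adjusted p = 0.995). Of the 23 measured granulocyte-monocyte progenitor genes, 12 rose adjusted over the list alone (median 0.76, camera adjusted p = 1.63e-14, and adjusted p = 0.15 with an estimated correlation). Among them were Mpo (myeloperoxidase, 2.47, SE 0.45), Ctsg (cathepsin G, 2.51, SE 0.41), Hp (haptoglobin, 2.11) and Igsf6 (1.82), while Elane (neutrophil elastase) differed by 0.96 (SE 0.36, adjusted p = 0.751 over all genes). The monocyte, macrophage and dendritic cell list was also higher, by a median of 0.13 (camera adjusted p = 0.00225, and adjusted p = 0.367 with an estimated correlation), with 0 of 23 members past the threshold adjusted over the list alone. Its members with the smallest p were Lyz2 (lysozyme, 1.16, SE 0.31) and F13a1 (0.72, SE 0.21), and Ccr2 differed by 0.86 (SE 0.27). Without PBS replicate 1 its adjusted p was 0.0687, and its median was 0.08 without G-CSF replicate 2 but 0.24 without PBS replicate 2, 0.26 without PBS replicate 3 or G-CSF replicate 1 and 0.27 without G-CSF replicate 3. With the dimmest 50% of probesets left out it was 0.35. Over all 14994 genes, 0 members of any of the 31 lists passed.

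**Figure D2:**
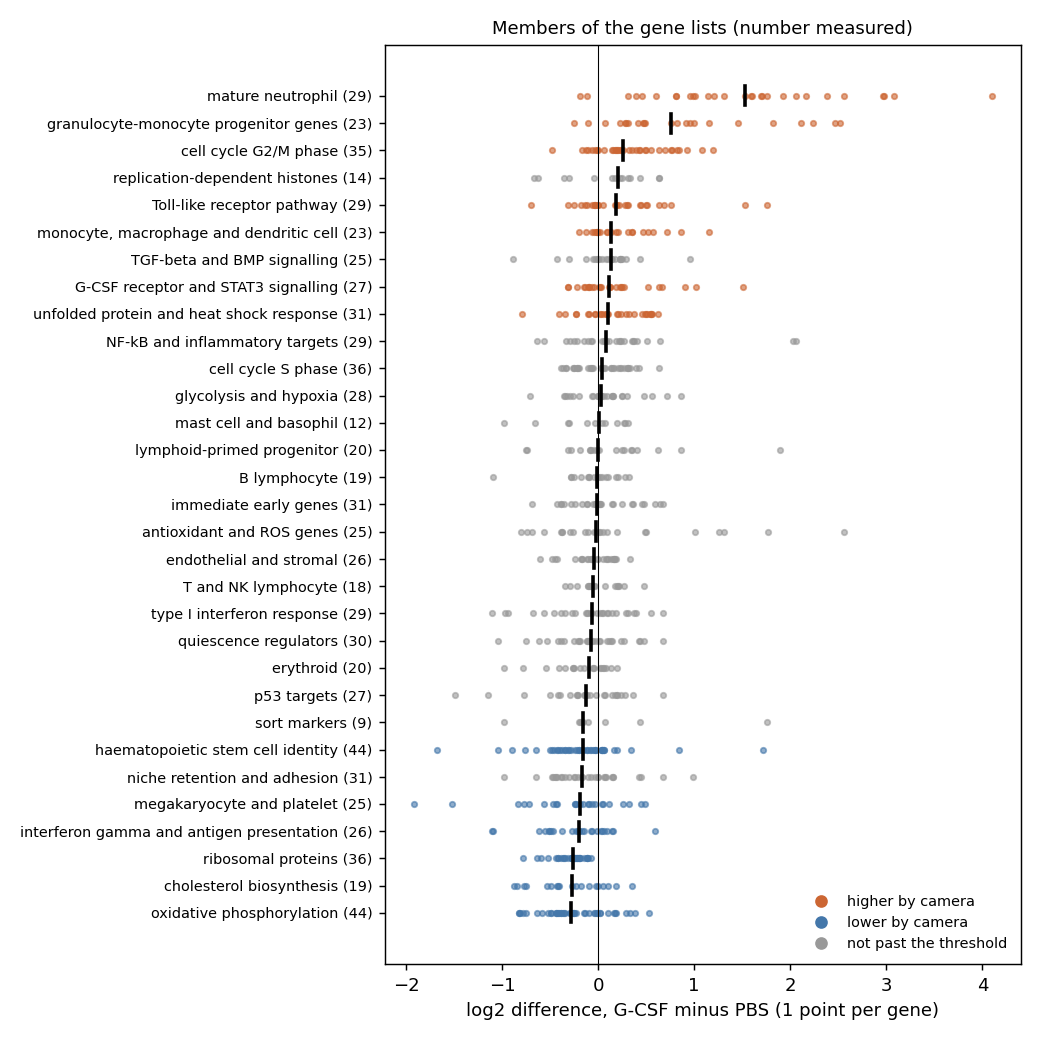
Log2 difference between G-CSF and PBS (horizontal axis) for each measured member of the 31 gene lists, with 1 point per gene, a black bar at each list's median and the number of measured members in brackets. Orange lists were higher and blue lists lower by camera with a preset correlation, and grey lists did not pass, with medians from 1.53 for mature neutrophil genes to -0.28 for oxidative phosphorylation.

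The Toll-like receptor pathway list was higher with G-CSF by a median of 0.19 (camera adjusted p = 0.00619, and adjusted p = 0.15 with an estimated correlation). Of its 29 measured members, 2 rose adjusted over the list alone, both of them receptors. Tlr1, whose 3 PBS arrays lay under the limit of 5.152, rose by at least 1.63 (adjusted p = 0.0627 over all genes) and Tlr13 by 1.53 (SE 0.32). Over all genes Tlr1 passed with quantile normalization again (adjusted p = 0.043) and with trend and robust settings (adjusted p = 0.0328), in a range of 0.0328 to 0.227 over its alternatives. Tlr6, which pairs with Tlr2, differed by 0.69 (SE 0.25), Map3k7 by 0.63 (SE 0.24), Tlr2 by 0.44 (SE 0.19), the adaptor Myd88 by 0.76 (SE 0.35) and the lipopolysaccharide receptor Tlr4 by 0.30 (SE 0.46), none past the threshold. Not all members rose, as 17 of the 29 had positive and 12 had negative differences. Traf6 differed by -0.70 (limma unadjusted p = 0.0387) and did not pass adjusted over the list alone either. The list's mean rose from 6.39 ± 0.04 to 6.63 ± 0.06 (SD, n = 3), with all G-CSF arrays above all PBS arrays. The median was 0.07 without PBS replicate 1 and 0.05 without G-CSF replicate 3, with adjusted p = 0.0265 and 0.0311. The mature neutrophil list moved in the same direction, from 7.56 ± 0.38 to 9.07 ± 0.28. NF-kB and inflammatory targets did not pass by camera (median 0.09, camera adjusted p = 0.0674) but did by fry's mixed test (adjusted p = 0.0125). In that list 1 of 29 members, Lcn2 (lipocalin 2, 2.06, SE 0.33), rose adjusted over the list alone, and Lcn2 is also a member of the mature neutrophil list. Il1b (interleukin 1 beta) differed by 2.03 (SE 0.48). The NF-kB list passed camera without G-CSF replicate 2 (median 0.17, adjusted p = 0.0213) or G-CSF replicate 3 (median 0.175, adjusted p = 0.0285), and with quantile normalization again (median 0.11, adjusted p = 0.0334).

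Genes of the G-CSF receptor and STAT3 pathway were higher as a list by a median of 0.11 (camera adjusted p = 0.0225, and adjusted p = 0.45 with an estimated correlation), with 0 of 27 members past the threshold adjusted over the list alone. The receptor gene Csf3r differed by 1.51 (SE 0.41, adjusted p = 0.477), with 6.61 ± 0.05 in PBS and 8.12 ± 0.89 in G-CSF arrays. Stat3 differed by 0.91 (SE 0.20), Il4ra by 1.02 (SE 0.25) and the feedback inhibitor Socs3 by 0.52 (SE 0.18). The mature neutrophil list moved with this list, and within each group both had their highest array mean in replicate 2. The list's call was lost without PBS replicate 1 (median 0.07, adjusted p = 0.0731), PBS replicate 3 (median 0.09, adjusted p = 0.105) or G-CSF replicate 2 (median 0.03, adjusted p = 0.234), and with ranks in place of values (adjusted p = 0.122). Its array means overlapped between groups (exact two-sided permutation p = 0.2).

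Mitotic genes were higher with G-CSF, with a median of 0.26 over 35 members of the G2/M list (camera adjusted p = 1.78e-07, and adjusted p = 0.15 with an estimated correlation). Adjusted over the list alone, 3 members rose, namely the spindle checkpoint kinase Bub1 (at least 0.82, with 2 of 3 PBS arrays under the limit of 5.152), topoisomerase Top2a (0.77, SE 0.18) and Dlgap5 (0.92, SE 0.22). Mki67, a marker of cycling cells, differed by 1.08 (SE 0.30, adjusted p = 0.486). The S phase list did not pass (36 members, median 0.04, camera adjusted p = 0.844), nor did the replication-dependent histones (14 members, median 0.21, adjusted p = 0.154), which passed without PBS replicate 2 (median 0.34, adjusted p = 0.0393). The quiescence regulators did not pass either (30 members, median -0.08, adjusted p = 0.328). In that list Rbl2 (p130) differed by -0.62 (SE 0.14) and the cell cycle inhibitor Cdkn1c by -0.39 (SE 0.17). In these 3 lists, 0 members passed adjusted over the list alone. With the dimmest 50% of probesets left out the G2/M median was 0.41. Arrays with more G2/M signal belonged to the group with more neutrophil and progenitor signal. Within groups this was mixed. PBS replicate 2 had the lowest G2/M mean of its group (6.080) and the highest mature neutrophil mean (7.875), while G-CSF replicate 2 had the highest of both (6.617 and 9.356).

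Stem cell identity genes were lower as a list, by a median of -0.16 over 44 members (camera adjusted p = 0.00225, and adjusted p = 0.367 with an estimated correlation). Adjusted over the list alone, Trpc6 fell by 1.68 (SE 0.35), while 2 members went the other way. Gda (guanine deaminase) rose by 1.72 (SE 0.25) and Ifitm1 by 0.84 (SE 0.16). Hmga2, a chromatin protein, differed by -0.76 (SE 0.19), and the surface markers Procr (-0.50, SE 0.28) and Slamf1 (CD150, -0.20, SE 0.20) did not pass. Without G-CSF replicate 1, the array with the lowest mean of this list (7.38), the median was -0.10 and the adjusted p 0.0931. Among the 9 measured sort markers, Kit, the receptor used as c-Kit in the gate, fell by 0.98 (SE 0.23) and Itgam, the myeloid integrin CD11b, rose by 1.76 (SE 0.44), both adjusted over the list alone. Cd48 (-0.11, SE 0.46) and Itga2b (CD41, -0.16, SE 0.15) did not pass. The sort marker list as a whole did not pass (camera adjusted p = 0.836, median -0.16 and mean 0.05). Niche retention and adhesion genes did not pass by camera (31 members, median -0.16, adjusted p = 0.154, 0 members adjusted over the list alone), with Cxcr4 at -0.44 (SE 0.47), Itga4 at -0.64 (SE 0.19) and Itgb2 at 0.99 (SE 0.25). By fry's mixed test for change in either direction, this list (adjusted p = 0.00189) and the sort marker list (0.0125) did pass.

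Megakaryocyte and platelet genes were lower by a median of -0.19 over 25 members (camera adjusted p = 0.0035, and adjusted p = 0.15 with an estimated correlation). Adjusted over the list alone, Pf4 fell by 1.92, Mmrn1 fell by 1.53 and Rab27b fell by 0.72 (SE 0.17). Of the 25 members, 18 had negative and 7 had positive differences. All G-CSF arrays lay below all PBS arrays in 6 members and above them in 3. Itgb3, 1 of these 3, differed by 0.45 (SE 0.15) and did not pass. Outside the neutrophil, progenitor and monocyte lists given above, markers of the other lineages that a marrow gate could hold did not pass as lists by camera. The erythroid list had a median of -0.10 (20 members, camera adjusted p = 0.106), with Car2 at -0.78 (SE 0.23). It passed camera without PBS replicate 1 (median -0.15, adjusted p = 0.00692) and with no filter on dim probesets (median -0.14, adjusted p = 0.0118). With the dimmest 50% of probesets left out it passed too (median -0.27, adjusted p = 0.0379). The median was -0.01 for B lymphocyte genes (19 members, adjusted p = 0.696, Cd72 at -1.09), -0.05 for T and NK lymphocyte genes (18 members, mean 0.01, adjusted p = 0.974) and -0.04 for endothelial and stromal genes (26 members, adjusted p = 0.556). For mast cell and basophil genes it was 0.006 (12 members, mean -0.10, adjusted p = 0.453). Adjusted over the list alone, 0 members of the first 4 of these lists passed, and Kit fell in the mast cell list.

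**Figure D3:**
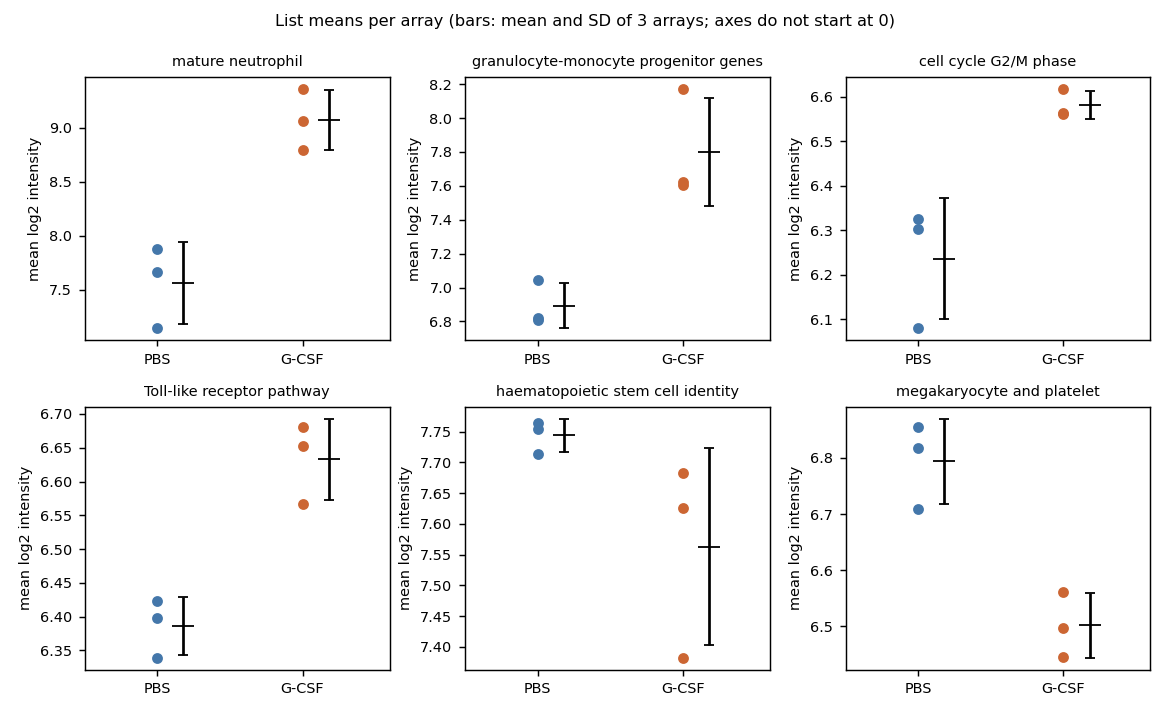
Mean log2 intensity of 6 gene lists (vertical axes, which do not start at 0) with 1 point per array for the 3 PBS and 3 G-CSF arrays, and bars for each group's mean and SD. In each of the 6 lists the groups do not overlap, with the largest gap in the mature neutrophil list, from 7.56 to 9.07. The 6 lists are a selection. The G-CSF receptor, unfolded protein, ribosomal protein, oxidative phosphorylation and cholesterol lists, also called by camera, overlapped between groups and are not drawn.

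Ribosomal protein, oxidative phosphorylation and cholesterol biosynthesis genes were lower with G-CSF as lists. All 36 measured ribosomal protein genes had negative differences, with a median of -0.26 (camera adjusted p = 1.93e-08, and adjusted p = 0.367 with an estimated correlation). The array means of that list overlapped between groups, and an exact two-sided permutation test of them gave p = 0.2, where 0.1 is the smallest p that 3 against 3 arrays allow (adjusted p = 0.388 over 31 lists). The same exact permutation test gave p = 0.5 (adjusted p = 0.62) for oxidative phosphorylation and p = 0.2 (adjusted p = 0.388) for cholesterol biosynthesis, whose array means overlapped too. With that smallest p, 0 of the 31 lists passed this exact permutation test after adjustment, and the adjusted p was 0.31 for the mature neutrophil, progenitor, G2/M, Toll-like receptor, monocyte, stem cell, megakaryocyte and interferon gamma lists. It was 0.31 too for the NF-kB and p53 target lists, which camera did not call. Rpl22 (-0.59, SE 0.22) and Rpl14 (-0.64, SE 0.25) had the smallest p in the ribosomal protein list. Oxidative phosphorylation genes had a median of -0.28 over 44 members (camera adjusted p = 0.0021, and adjusted p = 0.522 with an estimated correlation), among them Ndufb9 (-0.52, SE 0.18) and Sdha (-0.40, SE 0.15). Cholesterol biosynthesis genes had a median of -0.27 over 19 members (camera adjusted p = 0.00657, and adjusted p = 0.367 with an estimated correlation), with Nsdhl at -0.77 (SE 0.25) and Insig1 at -0.84 (SE 0.28). Adjusted over the list alone, 0 members of these 3 lists passed. G-CSF replicate 1 had the lowest array mean in all 3 lists and the lowest score on the first principal component (-34.7), and without it the ribosomal median was -0.16 (adjusted p = 0.000341). That replicate also had the lowest SD of log2 intensity over all probesets (1.79). Within each group, the array means of the ribosomal and oxidative phosphorylation lists ranked as that SD did. Both calls were kept with quantile normalization again. The oxidative phosphorylation call was lost without PBS replicate 3 (median -0.10, adjusted p = 0.176) or G-CSF replicate 1 (median -0.10, adjusted p = 0.439). The cholesterol call was lost without PBS replicate 2 (median -0.15, adjusted p = 0.125) or G-CSF replicate 1 (median -0.16, adjusted p = 0.0897), and its median was -0.41 with the dimmest 50% of probesets left out.

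Interferon gamma and antigen presentation genes were lower by a median of -0.20 over 26 members (camera adjusted p = 0.00739, and adjusted p = 0.213 with an estimated correlation). The members with the smallest p were the GTPase genes Iigp1 (-1.11, SE 0.27) and Gbp3 (-0.61, SE 0.21). Type I interferon response genes did not pass by camera (29 members, median -0.06, camera adjusted p = 0.328) but did by fry's mixed test (adjusted p = 0.0197), with Ifit3 at -1.10 (SE 0.29). The unfolded protein and heat shock list was higher by a median of 0.11 over 31 members (camera adjusted p = 0.00657, and adjusted p = 0.367 with an estimated correlation), with Dnajc3 at 0.55 (SE 0.17) and Chac1 at 0.51 (SE 0.17). In these 3 lists, 0 members passed adjusted over the list alone. The interferon gamma call was lost without G-CSF replicate 3 (median -0.10, adjusted p = 0.0838), and its median was -0.11 without G-CSF replicate 1. The unfolded protein call was lost without PBS replicate 1 (adjusted p = 0.0681) or G-CSF replicate 3 (adjusted p = 0.0759). Its array means overlapped (exact two-sided permutation p = 0.3), and its median was 0.18 without PBS replicate 3, 0.20 without G-CSF replicate 1, 0.18 with array weights and 0.17 with quantile normalization again.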

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

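The test without members shared between lists was chosen after seeing the data, and the other alternatives before. The number of genes higher, 4, was 12 with quantile normalization again, all 4 among them, and 2 with arrays centred on the median, both among the 4. It ranged from 0 to 6 when 1 array was left out, being 0 in 5 of 6 cases, where fewer arrays enter the fit. Otherwise it was 4 to 6, and the number of genes lower was 0 under every alternative run. Of the gene lists, 7 were higher and 6 lower. Both numbers were 0 with camera at an estimated correlation and 0 with fry. When 1 array was left out, lists higher ranged from 4 (without PBS replicate 1) to 8 and lists lower from 3 (without G-CSF replicate 1) to 7. The cause of these changes was not tested. Under both normalizations, both filters, the variance model, array weights and the probeset rule, all 7 and all 6 lists kept their calls. Replicate numbers were not taken as pairs, because the labels state no shared day or litter and 1 of the 3 correlations between deviations of same-numbered arrays (0.29, 0.02 and 0.19) was under 0.1. The other 2 were the highest of all 9, and G-CSF replicate 2 correlated best with PBS replicate 3 (0.10), so pairing stays unsettled. With the replicate block 5 genes were higher, 3 of the 4 among them (Ly6a2 had an adjusted p of 0.0781, and Ifitm6 passed at 0.0369), 0 were lower, genes at an unadjusted p under 0.05 went from 905 to 1210, and 7 and 6 lists kept their calls. Of 1253 gene values under alternatives, 1223 stayed on their side of the threshold, 24 lost it and 6 gained it, and 7 changed sign, all in the genes Cd48, Cxcr4, Ly6g and Tlr4, which were not called. Of 558 list values, 512 stayed, 39 lost and 7 gained the threshold, and 19 changed direction, none of them called. Signal over background limits dim genes, and the filter at a log2 mean of 5.152 stands in for a detection call.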

Other observations

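The tests of explanations in this part and the counts over other splits of the arrays were set down after their results were seen, except the covariate test of the Toll-like receptor list, and the tests of the gene lists themselves were planned. Among the antioxidant and reactive oxygen genes, 4 of 25 members rose and 1 fell adjusted over the list alone. The NADPH oxidase genes Cybb (2.56, SE 0.54), Ncf4 (1.31, SE 0.30) and Ncf1 (1.77, named after its value was seen) rose, as did glutathione reductase Gsr (1.26, SE 0.30), and the mitochondrial peroxiredoxin Prdx3 fell by 0.81 (SE 0.18). Cybb is also a member of the mature neutrophil list, whose median was 1.53, and the oxidase genes moved in its direction. The antioxidant list as a whole did not pass by camera (median -0.02, mean 0.18, camera adjusted p = 0.531) but did by fry's mixed test (adjusted p = 0.0218). In the lymphoid-primed progenitor list, 1 of 20 members, Cd52, rose by 1.90 (SE 0.36) adjusted over the list alone (median 0.00, camera adjusted p = 0.328). In the p53 target list Plk2 fell by at least 0.81 (all 3 G-CSF arrays lay under the filter's limit of 5.152) as 1 of 27 members (median -0.12, adjusted p = 0.16), and in the TGF-beta and BMP list Smad3 fell by 0.89 (SE 0.19) as 1 of 25 (median 0.13, adjusted p = 0.236), both adjusted over the list alone. Immediate early genes (31 members, median -0.01, mean 0.03, adjusted p = 0.731) and glycolysis and hypoxia genes (28 members, median 0.04, adjusted p = 0.532) did not pass, with 0 members adjusted over the list alone.

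Of 1132 probesets with several symbols and 6989 with none listed, 0 passed by limma at an adjusted p under 0.05, and 50 and 453 had an unadjusted p under 0.05. The smallest adjusted p was 0.0531, for a probeset with several symbols that was higher by 4.38 (SE 0.31).

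Neutrophil and granule genes were higher with G-CSF (median 1.53, bootstrap SE 0.24), a call lost with an estimated correlation (camera adjusted p = 0.15) and by fry (0.0681). A lower share of stem cells with more of every other cell type would raise the lists of other lineages too. Of the monocyte, erythroid, megakaryocyte, B, T and NK, mast cell and endothelial lists the highest median was 0.133 (monocyte, a list added to this test later, SE 0.095). None of these lists rose as far as the neutrophil list, in a test set down after these medians were seen. How far a list rises with more cells also depends on its level in the stem cells. Lists of other lineages hold genes of the stem cell fraction too, such as Kit in the mast cell list. The comparison therefore does not decide on a rise of every cell type. More of some cell types only is not covered by it, and camera called the monocyte list higher (adjusted p = 0.00225). Mature neutrophils alone would not bring genes of granule-forming progenitors that they no longer transcribe. Mpo, Prtn3, Ctsg and Ms4a3 were higher adjusted over the progenitor list alone (largest adjusted p = 0.0486), though not over all genes, and Elane did not pass (0.0529). An earlier form, unadjusted 95% intervals of all 5 against 0, would have excluded mature neutrophils alone and was replaced because genes had been picked for their high values. The division into 4 genes and Elane was made after these p-values were seen. Of the 5, only Mpo and Elane were named in advance, so the present form carries the same selection and decides nothing. Immature myeloid cells within the sorted pools, which the Sca-1 and CD48 gates should remove (progenitors that transcribe these genes are lineage-negative and c-Kit-positive), stay open, and the stem cell list decides nothing here, as its median of -0.16 (SE 0.06) was seen before the test and was -0.10 (adjusted p = 0.0931, range over alternatives 0.000385 to 0.367) without G-CSF replicate 1. A response of the stem cells themselves to G-CSF predicts the same rise and stays open, untested.

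Trpc6, Pf4, Mmrn1 and Rab27b were lower with G-CSF. Dilution of stem cell RNA by RNA of other cells would lower a gene by an amount that depends on its level in those cells. The 4 genes were set against the median of the other stem cell genes (-0.16, SE 0.06). That median is no ceiling on dilution, as 2 members of the stem cell list rose. By one-sided tests adjusted over the 67 genes of both lists, 0 of the 4 lay below that median less 2 SE (-0.27) at an adjusted p under 0.05 (0.0712 for Trpc6, Pf4 and Mmrn1, 0.262 for Rab27b). By one-sided tests 3 lay below the median itself (adjusted p = 0.0452, and 0.109 for Rab27b). As the median is no ceiling, neither comparison decides, and dilution stays open. An earlier form, each gene's unadjusted 95% interval against the median less 2 SE, would have been taken to exclude dilution. It was replaced because the genes had been picked for their low values. Fewer megakaryocytes or platelets, which the CD41 gate should remove, may also account for the pattern, and the other 22 megakaryocyte genes had a median of -0.13 (SE 0.08) within 2 SE of 0, so neither explanation can be told apart from a change in the stem cells.

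The Toll-like receptor list was higher with G-CSF by 0.25 in its mean per array (exact permutation p = 0.1, adjusted p = 0.31), and its camera call was lost with an estimated correlation (adjusted p = 0.15) and by fry (0.0681). If RNA of the cells that carry the neutrophil genes were the source, the difference would go to 0 with the neutrophil list as a covariate. With it, the difference was 0.074 (SE 0.099, 95% interval -0.24 to 0.39), and the slope on the neutrophil list was 0.12 (95% interval -0.08 to 0.31). With 3 residual degrees of freedom and a covariate that parts the groups itself, this source cannot be told apart from a change in Toll-like receptor expression of the stem cells, which may be G-CSF's effect.

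The 6 arrays make 10 splits into groups of 3, too few for a share under 0.05. The real split gave 4 genes higher and 0 lower, and the highest other split gave 1 gene in a direction. As many genes higher came from 1 of the 10 splits, the real one, and as many genes lower from all 10. The real split gave 7 lists higher and 6 lower, the highest other split gave 5 in a direction, and 1 of the 10 splits, the real one, reached each of these numbers. At an unadjusted p under 0.05 the real split had 905 genes, and the highest other split, which set G-CSF replicate 1 with PBS replicates 1 and 2, had 1064.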
